A study of Caenorhabditis elegans with 9 samples.

How the data were processed

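Gene expression was measured by RNA sequencing of poly(A) RNA from whole Caenorhabditis elegans in 3 groups of 3 libraries each. N2 is the Bristol wild type. WLZ1 carries an integrated transgene that expresses wild-type human LRRK2 in all neurons, and WLZ3 carries the G2019S form of LRRK2 in the same kind of transgene. Both transgenes use the promoter of the worm gene snb-1 and a lin-15(+) marker. Per the labels, the animals grew at 20 °C on Escherichia coli OP50, RNA was extracted with TRIzol, mRNA was captured on oligo(dT) beads, and paired-end libraries were sequenced on either of 2 named instruments. The stage, age and sex of the animals and the instrument of each library are not given in the sources used here. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

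The authors deposited 1 table of FPKM values (counts scaled by gene length and by a library total) for 28749 genes and the 9 libraries, and every column was matched to its sample by name. Per the submitters' processing notes, the tools were fastp 0.23.2, HISAT2 2.2.1 and featureCounts 2.0.3, on the worm genome build WBcel235. How FPKM was computed from the counts, and whether counting used the strand, is not given in the sources used here, so values of genes that overlap on opposite strands are uncertain. Gene names, types and positions came from the RefSeq gene table of that build, which matched 28744 genes and left 5 unmatched. In all, 26089 genes had a value above 0 in at least 1 library and 2660 were listed at 0 in every library. The human LRRK2 transcript was not analysed here.

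Depth was recovered from the values. FPKM times exon length, from Ensembl release 115, gave whole reads within a tolerance of 0.01 in every library for 25920 genes, 99.35% of those above 0. Of these genes, 23995 used the annotated exon length and 1925 another length. Library totals recovered in this way were 38128734, 47028842 and 49302679 reads for N2, 53336537, 50132430 and 53242513 for WLZ1 and 46142311, 44994277 and 51035227 for WLZ3. A library had 20181 to 21451 genes above 0, and 6 reads in a gene of 1 kb equalled 0.112 to 0.157 FPKM. Of counts from 2 to 20 reads, 80.59% to 85.4% were even, so both mates of a pair were mostly counted. Reads summed over genes came to 99.866% to 100.092% of the library totals, so the totals were close to the reads counted in genes. The floor for a gene at 0 was taken as 3 fragments of 2 reads per library, and floors cover counting error only. The 10 most abundant genes held 4.85% to 5.34% of a library's summed FPKM, mitochondrial DNA genes 0.794% to 1.12% and ribosomal RNA 0.16% to 0.461%. Replicate pairs differed by more than counting noise (chi-square per gene 11.4 to 32.4), so no pair was merged as copies of 1 library. This check does not show that the libraries are independent.

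Because the deposited unit was FPKM, the main test was limma (3.58.1, R 4.3.3) with an intensity trend on log2(FPKM + 1), fitted to all 9 libraries with 1 mean per group. Genes with at least 1 FPKM in at least 3 libraries were tested, which left 14862. Contrasts were WLZ1 minus N2, WLZ3 minus N2 and WLZ3 minus WLZ1. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05, two-sided. Changes are differences of log2(FPKM + 1), so they are compressed for genes near 0, and means with SD are given as FPKM. The overlap of the contrasts against N2 was the number of genes called in both in the same direction. It was compared with 50 simulations in which both strains shared the same N2 libraries and no gene changed. Data handling used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1.

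Before the data were examined, 45 gene lists of tissues, pathways and families were fixed, together with the contrasts, the tests, most alternatives and a rule for the genes to name. The 43 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, against all other genes. Some genes belong to several lists, such as myo-2 in muscle and pharynx, so the lists are not independent. Members were counted as called over all genes tested and, separately, with p-values adjusted over the list alone. The naming rule took lrk-1, snb-1, lin-15A and lin-15B. For each contrast it took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 FPKM in the higher group and no overlap between the groups' libraries. For each list called by camera or with at least 5 called members, it took up to 4 called members with the largest change. Where none was called, up to 2 members with the smallest p were taken, as values. A gene named in 1 contrast could be given in the others. Named genes outside the rule are said to be chosen after their values were seen.

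Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization, robust prior variances, a fit to the 2 groups compared, a block for the replicate number, an estimated correlation in camera, fry in place of camera, and leaving out each library in turn. With a library left out the filter still needed 3 libraries, so genes at 1 FPKM only in that library's group left the test. A fit of the recovered reads with limma-voom and a fit of protein-coding genes only were added after seeing the data. All 10 splits of the libraries of a comparison into 3 and 3, and 100 drawn splits of the 9 libraries for the overlap, were run in the same way. On simulated data, the fit recovered 40.8% of genes changed 1.5-fold, 73.9% of those changed 2-fold and 83.7% of those changed 4-fold, and 3.5% of its calls were false. In that simulation camera called the shifted list and 0 of 39 unshifted lists. Its genes were drawn independently, while the fixed lists had estimated correlations from -0.018 to 0.941. The simulation therefore does not show how often camera calls unchanged lists in these data. Splits of the real libraries other than the true grouping called 12 to 25 lists.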

Results

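Human LRRK2 is a kinase linked to Parkinson's disease, and its G2019S form has raised kinase activity. The data addressed how expression of either form in all neurons of the worm goes with gene expression in the whole animal. Whole worms of WLZ1 (wild-type LRRK2) and WLZ3 (LRRK2 G2019S) were compared with N2 and with each other, with 3 libraries per group.

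The worm genes carried by the transgenes as a marker were higher in both strains. lin-15B (chromosome X 15726129 to 15731861), a chromatin gene that restrains vulval fate, stood at 17.5 ± 0.624 FPKM in N2, 82.8 ± 5.53 in WLZ1 and 40.8 ± 2.64 in WLZ3 (mean ± SD, n = 3 here and throughout). Its neighbour lin-15A (X 15731968 to 15735365) stood at 16.8 ± 0.773, 74.5 ± 3.64 and 22.7 ± 0.387 FPKM. Against N2, lin-15B was 4.73-fold higher in WLZ1 and 2.33-fold higher in WLZ3 (limma adjusted p = 2.72e-07 and 2.42e-05), and lin-15A was 4.45-fold and 1.35-fold higher (adjusted p = 9.7e-08 and 0.0013). Both were lower in WLZ3 than in WLZ1, 2.03-fold for lin-15B (adjusted p = 1.6e-05) and 3.29-fold for lin-15A (adjusted p = 5.48e-07). The gene whose promoter drives the transgene, snb-1 (V 6655562 to 6656501), encodes the vesicle protein synaptobrevin and stood at 196 ± 11 FPKM in N2, 183 ± 12.4 in WLZ1 and 171 ± 6.17 in WLZ3. Its log2 change was -0.10 in WLZ1 (adjusted p = 0.172), a direction that turned to 0.09 with median-of-ratios scaling, and -0.20 in WLZ3 (adjusted p = 0.0343). The WLZ3 call was lost without N2 replicate 2 (adjusted p = 0.119), N2 replicate 3 (0.0643) or WLZ3 replicate 1, 2 or 3 (0.0746, 0.0536 and 0.101), and with no filter, a replicate block or median-of-ratios scaling (0.0597, 0.0695 and 0.0609). Between the strains snb-1 differed by -0.10 (adjusted p = 0.233), and by -0.23 with median-of-ratios scaling (adjusted p = 0.00641).

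The worm LRRK gene lrk-1 (I 10879769 to 10894237) stood at 7.57 ± 0.468 FPKM in N2, 5.49 ± 0.256 in WLZ1 and 6.89 ± 0.0354 in WLZ3. It was lower in WLZ1 than in N2 (log2 change -0.40, adjusted p = 0.00122) and higher in WLZ3 than in WLZ1 (0.28, adjusted p = 0.0154), with -0.12 in WLZ3 against N2 (adjusted p = 0.235). All 3 directions of lrk-1 turned with quantile normalization, to 0.18, -0.07 and 0.11, and the call between the strains was also lost with median-of-ratios scaling (0.16, adjusted p = 0.1). A short noncoding RNA gene upstream of snb-1, T10H9.10 (V 6659021 to 6659161, 2520 bases upstream), had 0 reads in each N2 library, 33.2 ± 2.37 FPKM in WLZ1 and 43.2 ± 4.09 in WLZ3. Against a floor of 3 fragments (6 reads) per library, it was at least 34.6-fold higher in WLZ1 and at least 44.9-fold higher in WLZ3. The next protein-coding gene upstream, pmp-5, stood at 33.8 ± 1.96 FPKM in N2, 29.2 ± 2.67 in WLZ1 and 30.4 ± 2.37 in WLZ3.

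**Figure D1:**
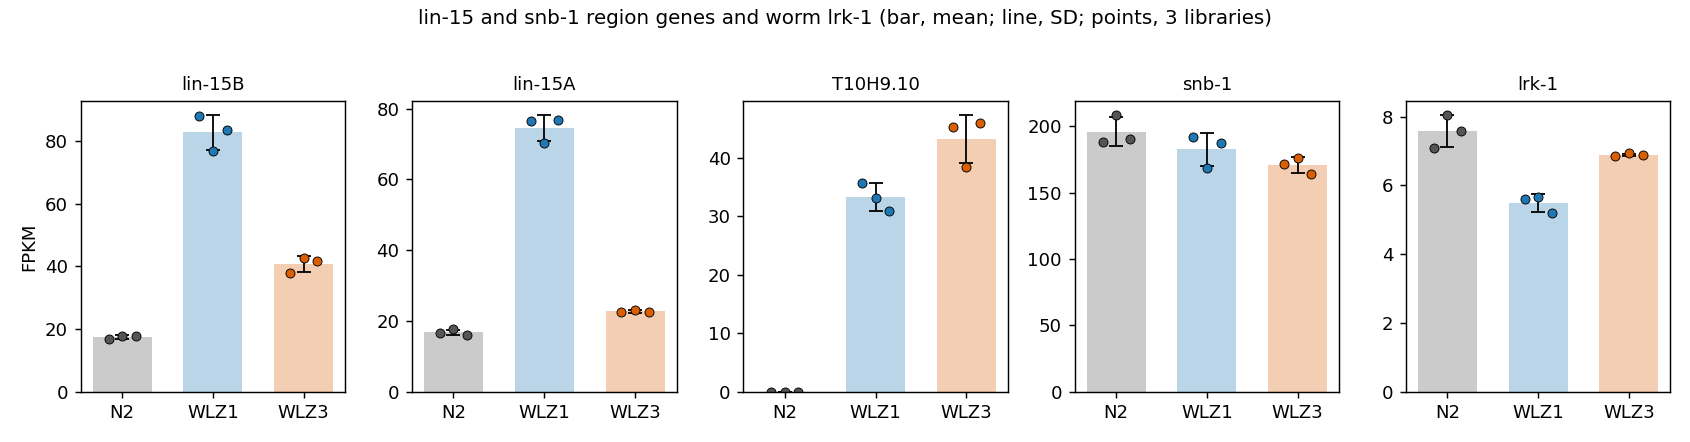
Mean FPKM (bars), SD (lines) and the 3 libraries (points) of lin-15B, lin-15A, T10H9.10, snb-1 and lrk-1 in N2, WLZ1 and WLZ3. lin-15B rose from 17.5 FPKM in N2 to 82.8 in WLZ1 and 40.8 in WLZ3, and T10H9.10 had 0 reads in N2, while the direction of snb-1 in WLZ1 and of lrk-1 turned with median-of-ratios scaling and with quantile normalization, respectively.

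**Figure D2:**
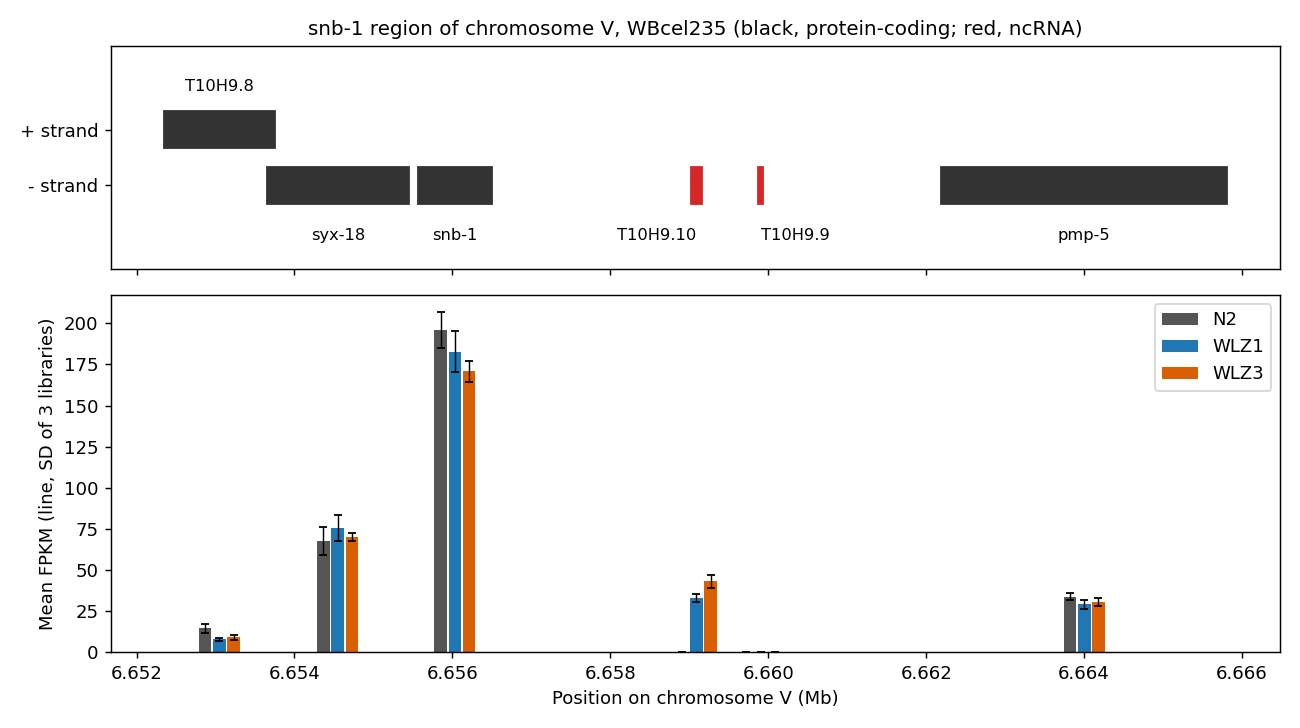
Genes on both strands around snb-1 on chromosome V in WBcel235 (upper panel, position in Mb) and their mean FPKM with SD in the 3 groups (lower panel, bars at each gene's place). T10H9.10, between snb-1 and pmp-5, reached 33.2 FPKM in WLZ1 and 43.2 in WLZ3, with 0 reads in N2.

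In WLZ1, genes of the nervous system, muscle, pharynx and cuticle were lower than in N2, and genes of the germ line, sperm and early embryo were higher. The cuticle collagen col-165 fell 14.2-fold, from 278 ± 76.3 FPKM in N2 to 19.6 ± 5.19 in WLZ1. The synaptotagmin snt-1, the calcium sensor of transmitter release, fell from 13 ± 1.54 to 3.03 ± 0.578 FPKM, and the troponin T gene tnt-4 from 78.5 ± 11.2 to 11.9 ± 1.71. The sperm gene msp-57 rose from 2.66 ± 1.92 to 81.3 ± 12.4 FPKM, and cyb-2.1, a cyclin B of dividing germ cells and embryos, from 119.1 ± 6.128 to 174 ± 4.17. Of 14862 genes tested, 10051 (67.6%) were called, 3949 higher and 6102 lower, and 2844 of these changed at least 2-fold (599 higher, 2245 lower). The groups' libraries did not overlap for 70.8% of the genes, where chance gives 10%. The balance of directions moved with scaling: 39.3% of called genes were higher as deposited, 53.6% with median-of-ratios scaling and 56.5% with quantile normalization. The median change of all tested genes was -0.13 as deposited, 0.03 with median-of-ratios scaling and 0.07 with quantile normalization. Relative to that median, the deposited values gave -1.196 for synaptic vesicle genes, -1.05 for muscle, -1.34 for collagens, 0.43 for the germ line and 0.52 for oocytes and early embryos.

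Neuronal genes were lower in WLZ1 across several lists. Counts of rises and falls are over all genes tested, and where no second count is given the count adjusted over the list alone was the same. Among 37 measured genes of synaptic vesicle release, 3 rose and 30 fell (3 and 31 adjusted over the list alone), with a median log2 change of -1.32 (camera adjusted p = 1.15e-06, and adjusted p = 0.409 with an estimated correlation). rbf-1 (III 6675760 to 6703998), the rabphilin that binds RAB-3 on vesicles, fell from 3.75 ± 0.247 to 0.0633 ± 0.0239 FPKM, and rab-3 itself from 26.9 ± 6.85 to 7.08 ± 0.613 FPKM (adjusted p = 4.15e-05). For 126 neuropeptide genes and their processing enzymes, 4 rose and 103 fell (4 and 105 adjusted over the list alone). Their median log2 change was -0.80 (camera adjusted p = 2.1e-09, and adjusted p = 0.409 with an estimated correlation). The neuropeptide nlp-39 fell from 210.5 ± 16.09 to 17 ± 3.04 FPKM (adjusted p = 1.75e-06), the insulin-like peptide ins-19 from 20.8 ± 6.76 to 3.9 ± 0.836 (adjusted p = 2.66e-05) and ida-1, a membrane protein of dense-core vesicles, from 37.6 ± 5.57 to 11.07 ± 1.07. Pan-neuronal markers gave 4 rises and 16 falls in 23 genes (4 and 16 adjusted over the list alone), with a median of -0.90 (camera adjusted p = 0.00853, and adjusted p = 0.409 with an estimated correlation). The tau-like gene ptl-1 fell from 12.06 ± 2.03 to 2.33 ± 0.519 FPKM, and mec-7 and mec-12, tubulins of the touch receptor neurons, fell from 21.7 ± 2.48 to 5.63 ± 0.637 and from 18.4 ± 1.78 to 4.83 ± 0.944. In the dopamine list 12 of 16 genes fell and 0 rose, with a median of -0.58, and camera did not call it (adjusted p = 0.0503). The dopamine transporter dat-1 fell from 1.68 ± 0.446 to 0.503 ± 0.0692 FPKM (adjusted p = 0.000797) and the vesicular monoamine transporter cat-1 from 1.66 ± 0.314 to 0.49 ± 0.156 (adjusted p = 0.000499). Glial markers, a list that also holds the neuronal glutamate receptor gene glr-1, fell in 11 of 12 genes. Across this list the median was -0.99 (camera adjusted p = 0.00597, adjusted p = 0.409 with an estimated correlation, and 0.169 with the filter at a mean of 5 FPKM). One of them, daf-6, which shapes the channel around sensory endings, fell from 3.3 to 0.518 FPKM.

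Muscle and body surface genes fell together in WLZ1. Contractile proteins of muscle gave 1 rise and 33 falls in 34 genes (the same counts adjusted over the list alone). The list median was -1.18 (camera adjusted p = 2.72e-09, and adjusted p = 0.409 with an estimated correlation). The troponin I gene tni-1 fell from 118 ± 11.2 to 22.9 ± 3.63 FPKM (adjusted p = 3.22e-06), and myo-2, a myosin of the pharynx, from 30 ± 6.12 to 5.7 ± 0.785. Genes of the pharyngeal glands and pharyngeal cuticle fell in 37 of 38 cases with 0 rises, with a median of -1.32 (camera adjusted p = 8.44e-09, and adjusted p = 0.409 with an estimated correlation). This list also holds pharyngeal muscle genes such as myo-1 and myo-2, which the muscle list shares. The gland gene phat-5 fell from 38.7 ± 12.25 to 2.59 ± 1.06 FPKM. Cuticle collagens fell in 101 of 133 genes with 0 rises (102 and 0 adjusted over the list alone). The median log2 change was -1.47 (camera adjusted p = 2.48e-09, and adjusted p = 0.409 with an estimated correlation). The moulting and apical matrix list gave 2 rises and 102 falls in 113 genes (3 and 105 adjusted over the list alone), with a median of -1.19 (camera adjusted p = 1.19e-12, and adjusted p = 0.409 with an estimated correlation). Its cuticlins cut-2 and cut-3, structural proteins of the cuticle, fell from 321 ± 60.1 to 23.2 ± 7.39 and from 111.6 ± 21.9 to 7.8 ± 2.78 FPKM. Epidermal markers fell in 17 of 19 genes with 0 rises. Across this list the median was -1.15 (camera adjusted p = 7.2e-05, and adjusted p = 0.409 with an estimated correlation). The hedgehog-like gene wrt-2 fell from 24.9 ± 1.99 to 3.33 ± 0.487 FPKM and the collagen gene dpy-7 from 78 ± 8.82 to 20.9 ± 6.1. Intestinal markers fell in 12 of 25 genes with 0 rises, with a median of -0.27, and camera did not call the list (adjusted p = 0.0564). The intestinal filament gene ifb-2 fell from 59.2 ± 5.12 to 18.2 ± 1.14 FPKM (adjusted p = 3.03e-06). Among uncharacterized genes, C02E7.7 fell 18.7-fold (171 ± 10.8 to 9.15 ± 4.48 FPKM) and C54C8.12 fell from 212 ± 31.7 to 11.4 ± 1.59 FPKM.

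Germ line, DNA replication, proteasome and synMuv lists were higher in WLZ1 by smaller amounts, apart from sperm genes. All 27 measured genes for the major sperm protein, the cytoskeletal protein of crawling sperm, rose, with a median of 4.06 (27 adjusted over the list alone, camera adjusted p = 4.62e-11, and adjusted p = 0.409 with an estimated correlation). These genes are near-identical in sequence, so the split of reads between them is uncertain. In the other sperm genes 33 rose and 11 fell of 56. The list median was 0.82 (camera adjusted p = 8.72e-05, adjusted p = 0.47 with an estimated correlation, and 0.224 with the filter at a mean of 5 FPKM). One of these, nspd-2, of another family of near-identical genes, rose from 4.11 ± 4.68 to 93.1 ± 9.56 FPKM (adjusted p = 0.00204). Oocyte and early embryo genes rose in 33 of 36 cases with 0 falls (33 and 1 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 2.93e-11, and adjusted p = 0.409 with an estimated correlation). puf-11, a Pumilio protein that controls translation in oocytes, rose from 170 ± 2.16 to 240 ± 7.77 FPKM. Of the germ line and P granule list, 30 of 37 genes rose and 1 fell (31 and 1 adjusted over the list alone). Their median log2 change was 0.30 (camera adjusted p = 1.24e-09, and adjusted p = 0.409 with an estimated correlation). In this list the Argonaute gene csr-1 rose from 80.6 ± 5.06 to 110 ± 3.64 FPKM. The germ cell gene nos-2, of the oocyte and early embryo list, rose from 157 ± 18.6 to 233 ± 6.41 FPKM (adjusted p = 0.000363). DNA replication and cell cycle genes rose in 32 of 34 cases with 0 falls, with a median of 0.27 (camera adjusted p = 5.12e-10, and adjusted p = 0.409 with an estimated correlation), among them the condensin gene smc-4 (51.7 ± 1.13 to 67 ± 2.06 FPKM). Proteasome subunits rose in 31 of 34 cases with 0 falls (33 and 0 adjusted over the list alone). The median log2 change was 0.31 (camera adjusted p = 4.19e-11, and adjusted p = 0.409 with an estimated correlation). The gene rpn-9 of the proteasome lid rose from 148 ± 0.365 to 222 ± 22.4 FPKM. The synMuv chromatin list, which holds lin-15A and lin-15B, gave 15 rises and 0 falls in 22 genes. The list median was 0.22 (camera adjusted p = 1.97e-05, and adjusted p = 0.409 with an estimated correlation). In the germ line and P granule list, mes-6, which encodes a Polycomb protein, rose from 33.5 to 47.8 FPKM. Yolk protein genes rose in 3 of 6 cases, with a median of 0.42, and camera did not call them (adjusted p = 0.0503).

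Defence, stress and LRRK2-related lists moved less evenly in WLZ1. Lysozymes and antimicrobial peptides gave 9 rises and 63 falls in 86 genes, with a median of -0.81 (camera adjusted p = 0.00067, and adjusted p = 0.409 with an estimated correlation). The saposin-like gene spp-27 fell from 7.04 ± 2.29 to 0.0318 ± 0.055 FPKM. The abu and pqn genes gave 7 rises and 35 falls in 55 (7 and 36 adjusted over the list alone). Their median log2 change was -0.75 (camera adjusted p = 0.00221, and adjusted p = 0.409 with an estimated correlation). In this list abu-14 fell from 104.3 ± 17.9 to 9.16 ± 2.76 FPKM. Glutathione S-transferases fell in 24 of 38 cases with 0 rises, with a median of -0.40 (camera adjusted p = 0.0155, adjusted p = 0.409 with an estimated correlation, and 0.161 with quantile normalization). C-type lectins gave 39 rises and 35 falls in 115 genes. The median was 0.03 and the mean 0.31, and camera called the list upward (adjusted p = 0.019, and adjusted p = 0.409 with an estimated correlation). That call was lost without WLZ1 replicate 1, 2 or 3, with medians of -0.15, -0.14 and -0.15 (adjusted p = 0.945, 0.71 and 0.841), with median-of-ratios scaling (adjusted p = 0.1) and with the filter at a mean of 5 FPKM, which turned the median to -0.14. Leaving out a WLZ1 library also took lectins at 1 FPKM only in WLZ1, such as clec-197, out of the test by the filter. Those 3 losses therefore do not show that the call rests on 1 library. The list of Rab GTPases and other genes linked to LRRK2, which also holds genes such as pink-1, pdr-1 and gba-3, gave 6 rises and 6 falls in 20 genes. The median was 0.06 and the mean -0.10 (camera adjusted p = 0.297). Among autophagy genes 4 rose and 13 fell of 36 (camera adjusted p = 0.567), including hlh-30, the worm TFEB that controls lysosome genes (53.3 to 30.2 FPKM, adjusted p = 4.47e-06), and sqst-1, an autophagy receptor (78.5 to 41.5 FPKM). The lysosome list gave 8 rises and 33 falls in 73 genes (8 and 32 adjusted over the list alone, camera adjusted p = 0.229), among them the cathepsin B gene cpr-4 (511 to 213 FPKM). The mitochondrial unfolded protein response list gave 8 rises and 4 falls in 20 (7 and 4 adjusted over the list alone, camera adjusted p = 0.176). The endoplasmic reticulum response list gave 7 rises and 11 falls in 26, with a median of -0.02 and an upward camera direction (adjusted p = 0.773). Heat shock genes gave 11 rises and 14 falls in 32 (12 and 14 adjusted over the list alone). The median was -0.04 and the mean -0.49 (camera adjusted p = 0.93).

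A further set of genes was near 0 in N2 and WLZ3 and abundant in WLZ1. K12H6.9 (II 2824404 to 2824957) stood at 0.334 ± 0.425 FPKM in N2, 42.6 ± 3.08 in WLZ1 and 0.742 ± 0.628 in WLZ3, and the insulin-like peptide gene ins-31 (II 3127041 to 3127831) at 0.419 ± 0.0882, 43.6 ± 8.02 and 0.833 ± 0.672 (adjusted p against N2 of 2.12e-06 for K12H6.9). The C-type lectin gene clec-197 stood at 0.568, 32 ± 5.42 and 0.558 FPKM. In all, 44 genes had at least 5 FPKM in every WLZ1 library and over 10 times the highest other library, a rule chosen after the values were seen. By that rule 1 gene, the pseudogene Y106G6E.3, stood out in WLZ3 (0.0472 FPKM in N2, 0.0381 in WLZ1 and 5.81 ± 0.355 in WLZ3), and 0 genes did in N2.

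**Figure D3:**
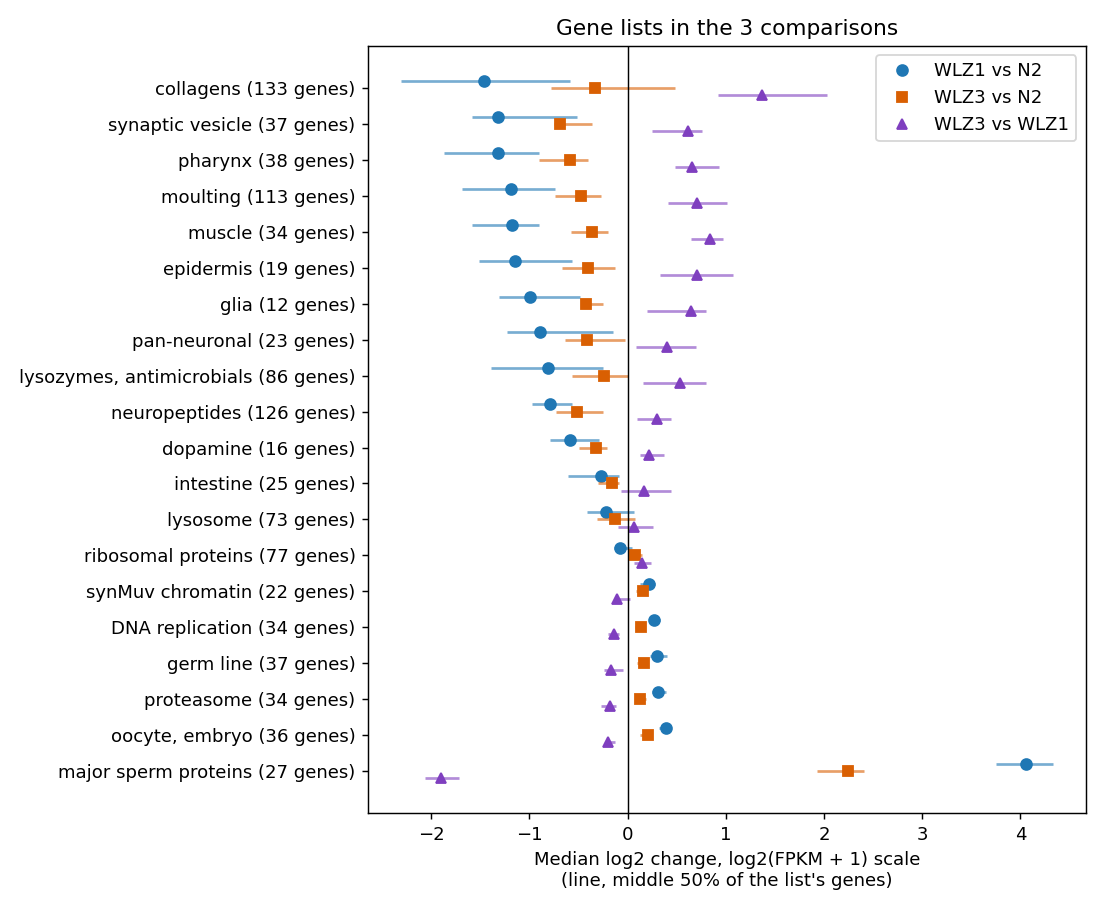
Median log2 change (points) and the middle 50% of members (lines) for 20 gene lists in the 3 comparisons. The collagen median was -1.47 in WLZ1 against N2, -0.33 in WLZ3 against N2 and 1.37 between the strains, and the major sperm protein median was 4.06, 2.24 and -1.90.

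**Figure D4:**
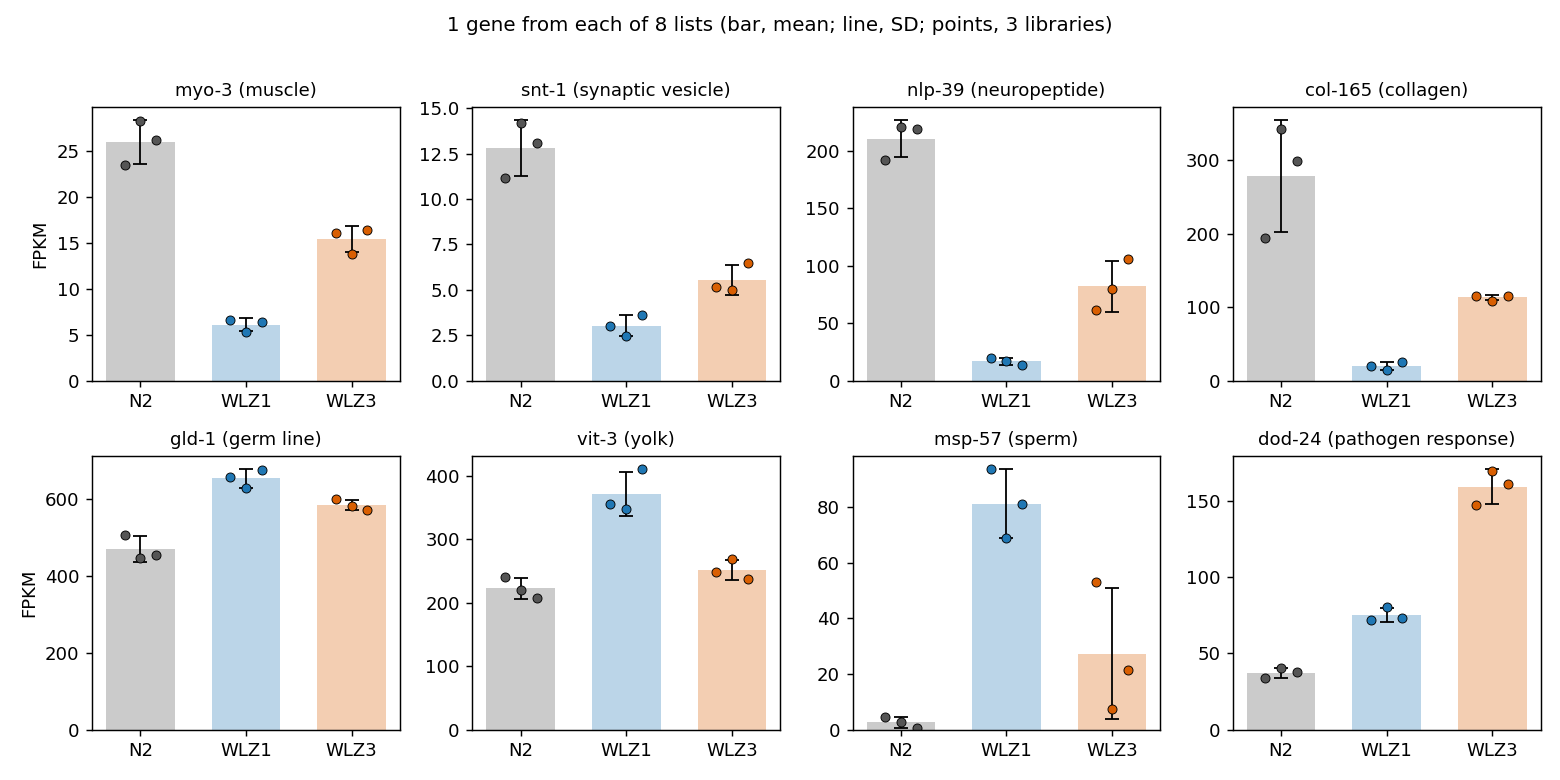
Mean FPKM (bars), SD (lines) and the 3 libraries (points) of 8 genes of muscle (myo-3), synapse (snt-1), neuropeptides (nlp-39), cuticle (col-165), germ line (gld-1), yolk (vit-3), sperm (msp-57) and defence (dod-24) in N2, WLZ1 and WLZ3. In WLZ3 the mean of nlp-39 (82.1 FPKM) lay between those of N2 (210.5 FPKM) and WLZ1 (17 FPKM), and dod-24 reached 159 FPKM in WLZ3.

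WLZ3 animals showed many of the same lists lower than in N2, by smaller amounts. snt-1 fell from 13 ± 1.54 FPKM in N2 to 5.54 ± 0.815 in WLZ3, nlp-39 from 210.5 ± 16.09 to 82.1 ± 22.1, and tnt-4 from 78.5 ± 11.2 to 32.1 ± 4.85. dod-24, a gene regulated by the insulin pathway and by infection, rose from 37.2 ± 3.24 to 159 ± 11.4 FPKM (log2 change 2.07, adjusted p = 1.9e-06). The inducible chaperone gene hsp-70 fell from 24.6 ± 3.89 to 5.11 ± 0.91 FPKM (adjusted p = 0.000125). The fit called 5354 of 14862 genes (36%), 1976 higher and 3378 lower, of which 429 changed at least 2-fold (160 higher, 269 lower), and 51.9% of genes had no overlap between the groups' libraries, where chance gives 10%. Without N2 replicate 2 the count was 3013, and without N2 replicate 3 it was 3204. Rises numbered 1095 without WLZ3 replicate 1, 1028 without N2 replicate 2 and 1117 without N2 replicate 3. The share of called genes that were higher was 36.9% as deposited, 49.8% with median-of-ratios scaling and 51.3% with quantile normalization, and the median change of all genes was -0.02 as deposited.

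Neuronal lists were lower in WLZ3 too. Synaptic vesicle genes gave 1 rise and 32 falls in 37 (1 and 32 adjusted over the list alone). The list median was -0.69 (camera adjusted p = 1.56e-09, and adjusted p = 0.298 with an estimated correlation). The complexin gene cpx-1, a clamp on vesicle fusion, fell from 36 ± 1.01 to 17.3 ± 2.46 FPKM. Neuropeptide genes gave 0 rises and 75 falls in 126 (1 and 85 adjusted over the list alone), with a median of -0.52 (camera adjusted p = 1.3e-12, and adjusted p = 0.298 with an estimated correlation). The peptide gene flp-15 fell from 27 ± 1.81 to 12.63 ± 1.81 FPKM. Pan-neuronal markers gave 0 rises and 14 falls in 23 (1 and 14 adjusted over the list alone). Their median log2 change was -0.42 (camera adjusted p = 0.00113, and adjusted p = 0.298 with an estimated correlation). The gene ptl-1 fell from 12.06 ± 2.03 to 5.1 ± 0.506 FPKM. The dopamine list gave 0 rises and 7 falls in 16 (1 and 8 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.0341, and adjusted p = 0.298 with an estimated correlation). dat-1 fell from 1.68 ± 0.446 to 0.731 ± 0.0569 FPKM (adjusted p = 0.0112) and the receptor gene dop-1 from 1.57 to 0.651 FPKM (adjusted p = 0.00771). The call on the dopamine list was lost without N2 replicate 1, 2 or 3 (adjusted p = 0.342, 0.0825 and 0.145) or WLZ1 replicate 2 (0.0518), with quantile normalization (0.053) and with the filter at a mean of 5 FPKM (0.366). Glial markers fell in 7 of 12 genes with 0 rises. Across this list the median was -0.42 (camera adjusted p = 0.00969, adjusted p = 0.449 with an estimated correlation, and 0.215 with the filter at a mean of 5 FPKM).

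Muscle and surface lists fell less in WLZ3 than in WLZ1, and collagens went both ways. Muscle gave 1 rise and 22 falls in 34 genes (1 and 23 adjusted over the list alone). The list median was -0.37 (camera adjusted p = 5.39e-06, and adjusted p = 0.449 with an estimated correlation). Pharyngeal myosin myo-2 fell from 30 ± 6.12 to 11 ± 1.51 FPKM. Pharyngeal gland and cuticle genes gave 0 rises and 27 falls in 38 (0 and 33 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 5.27e-09, and adjusted p = 0.298 with an estimated correlation). The moulting list gave 0 rises and 63 falls in 113 (0 and 69 adjusted over the list alone). Its median log2 change was -0.47 (camera adjusted p = 4.21e-11, and adjusted p = 0.298 with an estimated correlation). The cuticlin cut-2 fell from 321 ± 60.1 to 127 ± 7.64 FPKM. Epidermal markers gave 0 rises and 10 falls in 19 (0 and 11 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 0.000337, and adjusted p = 0.298 with an estimated correlation). The epidermal gene wrt-2 fell from 24.9 ± 1.99 to 12.33 ± 0.639 FPKM. Collagens gave 21 rises and 41 falls in 133 (23 and 46 adjusted over the list alone). The median was -0.33 and the mean -0.01, and camera did not call them (adjusted p = 0.396). Among them col-81, col-129 and col-139 had means of 69.9 ± 76.3, 64.1 ± 70.1 and 84.2 ± 93.7 FPKM in WLZ3 against 0.872 ± 0.442, 1.54 ± 0.251 and 1.44 ± 0.378 in N2 (adjusted p = 0.00654, 0.00994 and 0.00766). The spread within WLZ3 was wide, with col-81 at 154.85, 7.2 and 47.56 FPKM in replicates 1, 2 and 3, and all 3 calls were lost with limma-voom on recovered reads (adjusted p = 0.0923 for col-81, 0.076 for col-129 and 0.0801 for col-139).

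Germ line, DNA replication, proteasome and synMuv lists rose in WLZ3 by smaller amounts than in WLZ1. Major sperm protein genes rose in 26 of 27 cases (27 adjusted over the list alone). Across this list the median was 2.24 (camera adjusted p = 1.56e-09, and adjusted p = 0.379 with an estimated correlation). In replicates 1, 2 and 3 the members had medians of 2.32, 0.66 and 0.32 FPKM in N2 and 22.12, 2.89 and 7.3 in WLZ3, and the median log2 change was 1.538 without WLZ3 replicate 1. One member, msp-57, stood at 2.66 ± 1.92 FPKM in N2 and 27.4 ± 23.5 in WLZ3 (adjusted p = 0.0111). The other sperm genes gave 11 rises and 5 falls in 56 (11 and 4 adjusted over the list alone). Log2 changes had a median of 0.36 (camera adjusted p = 0.0146, and adjusted p = 0.651 with an estimated correlation). That call was lost without N2 replicate 3 (adjusted p = 0.0654), with median-of-ratios scaling (0.0563) and with the filter at a mean of 5 FPKM (0.321). Oocyte and early embryo genes gave 20 rises and 0 falls in 36 (23 and 0 adjusted over the list alone), with a median of 0.21 (camera adjusted p = 6.59e-09, and adjusted p = 0.298 with an estimated correlation). The germ line and P granule list gave 14 rises and 0 falls in 37 (20 and 0 adjusted over the list alone). Log2 changes had a median of 0.17 (camera adjusted p = 2.29e-06, and adjusted p = 0.298 with an estimated correlation). In this list csr-1 rose from 80.6 ± 5.06 to 97.2 ± 1.84 FPKM. gld-1, a repressor of translation in the germ line and a member of the oocyte and early embryo list, rose from 470 ± 33 to 585 ± 13.3 FPKM (adjusted p = 0.00471). DNA replication genes rose in 15 of 34 cases (median 0.13, camera adjusted p = 2.24e-06), synMuv genes in 9 of 22 (median 0.15, camera adjusted p = 2.2e-05) and proteasome subunits in 12 of 34 (median 0.13, camera adjusted p = 5.34e-07), each with 0 falls and each with adjusted p = 0.298 with an estimated correlation.

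Stress and defence genes went in different directions in WLZ3. Heat shock genes gave 1 rise and 13 falls in 32. The median was -0.16 and the mean -0.54 (camera adjusted p = 0.0126, and adjusted p = 0.298 with an estimated correlation). The small heat shock protein genes hsp-16.41 and hsp-16.2 fell from 39.4 ± 16.09 to 7.23 ± 1.14 and from 43 ± 17.3 to 8.32 ± 0.466 FPKM (adjusted p = 0.0017 and 0.000986). In WLZ1 they stood at 9.03 ± 2.64 and 11.4 ± 0.689 FPKM (adjusted p against N2 of 0.000405 and 0.000286) and hsp-70 at 11.06 ± 1.249 (0.000176), so all 3 were lower than N2 in both strains. Genes of the insulin pathway factor DAF-16 gave 0 rises and 11 falls in 25, with a median of -0.54 (camera adjusted p = 0.00313, and adjusted p = 0.298 with an estimated correlation). In WLZ1 the same list gave 4 rises and 14 falls, with a median of -0.46, and camera did not call it (adjusted p = 0.218). Between the strains its median was 0.016 (camera adjusted p = 0.378), so the falls were not particular to WLZ3. In WLZ3 the target dod-6 fell from 221 to 130 FPKM (adjusted p = 0.0016). The desaturase gene fat-7, from the lipid metabolism list, fell from 27 ± 2.66 to 12.4 ± 1.95 FPKM. That list gave 10 rises and 29 falls in 99 genes, and camera did not call it (adjusted p = 0.153). Lysozymes and antimicrobial peptides gave 5 rises and 32 falls in 86. Across this list the median was -0.24 (camera adjusted p = 0.00427, and adjusted p = 0.319 with an estimated correlation). The lysozyme gene lys-3 fell from 11 ± 2.44 to 1.49 ± 0.238 FPKM (adjusted p = 0.000332). The abu and pqn genes gave 3 rises and 32 falls in 55 (4 and 34 adjusted over the list alone). The median log2 change was -0.36 (camera adjusted p = 0.000321, and adjusted p = 0.31 with an estimated correlation). The pathogen response list gave 11 rises and 10 falls in 34 (13 and 10 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.0158, and adjusted p = 0.298 with an estimated correlation), a call lost without N2 replicate 1 (adjusted p = 0.0908) and with the filter at a mean of 5 FPKM (0.255). The infection response gene irg-6 rose from 7.94 ± 1.24 to 23.7 ± 3.77 FPKM (adjusted p = 0.000476). Glutathione S-transferases fell in 14 of 38 cases with 0 rises (camera adjusted p = 0.00932, and adjusted p = 0.298 with an estimated correlation). This call was lost without N2 replicate 1 (0.076).

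Mitochondrial DNA genes, which encode respiratory chain subunits, gave 2 rises and 0 falls in 12 in WLZ3 (2 and 0 adjusted over the list alone). Log2 changes centred on 0.24 (camera adjusted p = 0.0121, and adjusted p = 0.379 with an estimated correlation). CYTB rose from 1739 ± 173 to 2290 ± 121 FPKM (adjusted p = 0.00993) and ND6 from 23.6 ± 2.04 to 43.1 ± 0.919 (adjusted p = 0.000407). A further 4 lists passed camera in WLZ3 but were lost without several libraries. Intestinal markers (0 rises and 5 falls in 25, 0 and 4 adjusted over the list alone, median -0.16, adjusted p = 0.0397, and adjusted p = 0.298 with an estimated correlation) were lost without N2 replicate 1 (0.114), WLZ3 replicate 1 (0.0607) or WLZ3 replicate 3 (0.0505). The lysosome list (7 rises and 26 falls in 73, 7 and 27 adjusted over the list alone, median -0.13, adjusted p = 0.0397, and adjusted p = 0.298 with an estimated correlation) was lost without N2 replicate 1 (0.132), WLZ1 replicate 1 (0.0586) or WLZ3 replicates 1 or 3 (0.0738 and 0.0731). Cytochrome P450 genes (1 rise and 13 falls in 51, 1 and 12 adjusted over the list alone, median -0.21, adjusted p = 0.0397, and adjusted p = 0.571 with an estimated correlation) were lost without N2 replicates 1 or 3 (0.0864 and 0.0857), WLZ1 replicates 1 or 2 (0.0564 and 0.0518) or WLZ3 replicate 1 (0.158). Ribosomal protein genes (1 rise and 2 falls in 77, 0 and 1 adjusted over the list alone, median 0.08, adjusted p = 0.00398, and adjusted p = 0.651 with an estimated correlation) were lost without N2 replicate 3 (0.145) or WLZ3 replicate 1 (0.0738). Other settings also ended these calls, namely median-of-ratios scaling for the intestine (0.0807) and the lysosome (0.134), and quantile normalization and the filter at a mean of 5 FPKM for cytochrome P450 (0.456 and 0.123) and ribosomal proteins (0.63 and 0.0736). Yolk protein genes had 0 calls in WLZ3, with a median of 0.07 (camera adjusted p = 0.396).

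For some genes called in both strains, the difference between the strains did not pass the test. The uncharacterized gene C08F11.7 (IV 13637275 to 13638666) stood at 1.24 ± 0.201 FPKM in N2, 16.40 ± 1.77 in WLZ1 and 15.6 ± 1.26 in WLZ3, with log2 changes against N2 of 2.96 and 2.89 and a difference between the strains of -0.06 (adjusted p = 0.658). The immune gene sysm-1 stood at 63.2 ± 12.09, 167 ± 12.05 and 163.6 ± 9.87 FPKM, with -0.03 between the strains (adjusted p = 0.873).

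Between the transgenic strains, muscle, cuticle and neuronal genes were higher in WLZ3 than in WLZ1, and germ line and sperm genes were lower. The body wall muscle myosin gene myo-3 stood at 6.09 ± 0.685 FPKM in WLZ1 and 15.4 ± 1.38 in WLZ3 (25.9 ± 2.4 in N2). The ground-like gene grl-7 stood at 4.28 ± 0.487 and 18.9 ± 1.38 (40.3 ± 4.46 in N2). M199.9 (IV 15127446 to 15127831) stood at 1.45 ± 0.737 FPKM in WLZ1 and 51.5 ± 1.47 in WLZ3, and 12.5 ± 1.14 in N2. The yolk protein gene vit-3 was lower in WLZ3, at 252 ± 16.12 FPKM against 371 ± 34.3 in WLZ1 (adjusted p = 0.00095). The fit called 6259 genes (42.1%), 4393 higher in WLZ3 and 1866 lower, of which 1032 differed at least 2-fold (716 higher, 316 lower), and 55.7% of genes had no overlap between the groups' libraries, where chance gives 10%. Genes lower in WLZ3 numbered 1028 without WLZ1 replicate 1, 1202 without WLZ1 replicate 2 and 1079 without WLZ3 replicate 3. The share of called genes higher in WLZ3 was 70.2% as deposited, 45.9% with median-of-ratios scaling and 47.9% with quantile normalization, and the median of all genes was 0.10 as deposited.

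Muscle genes were higher in WLZ3 in 33 of 34 cases and lower in 1. Log2 changes had a median of 0.84 (camera adjusted p = 5.87e-11, and adjusted p = 0.415 with an estimated correlation). Troponin I (tni-1) rose from 22.9 ± 3.63 FPKM in WLZ1 to 63.9 ± 9.61 in WLZ3. Collagens were higher in 110 of 133 cases and lower in 0 (121 and 0 adjusted over the list alone). Log2 changes centred on 1.37 (camera adjusted p = 6.13e-16, and adjusted p = 0.415 with an estimated correlation). The moulting list gave 88 higher and 1 lower in 113 (94 and 1 adjusted over the list alone), with a median of 0.70 (camera adjusted p = 5.92e-12, and adjusted p = 0.415 with an estimated correlation). The cuticlin cut-3 went from 7.8 ± 2.78 to 43 ± 6.01 FPKM. Pharyngeal genes gave 29 higher and 0 lower in 38 (31 and 1 adjusted over the list alone, camera adjusted p = 1.12e-06), and epidermal markers 14 higher and 0 lower in 19 (15 and 0 adjusted over the list alone, camera adjusted p = 5.75e-05), each with adjusted p = 0.415 with an estimated correlation. dpy-7 went from 20.9 ± 6.1 to 52.2 ± 2.45 FPKM and abu-14 from 9.16 ± 2.76 to 49.3 ± 7.1. Synaptic vesicle genes gave 29 higher and 3 lower in 37 (29 and 3 adjusted over the list alone). The median log2 change was 0.61 (camera adjusted p = 0.000161, adjusted p = 0.459 with an estimated correlation, and 0.0941 with the filter at a mean of 5 FPKM). The rabphilin gene rbf-1 went from 0.0633 ± 0.0239 to 1.92 ± 0.114 FPKM. Neuropeptide genes gave 44 higher and 7 lower in 126 (39 and 6 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.00736, adjusted p = 0.566 with an estimated correlation, and 0.188 with quantile normalization). The insulin-like gene ins-19 went from 3.9 ± 0.836 to 27.6 ± 1.48 FPKM. Pan-neuronal markers gave 15 higher and 3 lower in 23 (17 and 3 adjusted over the list alone, median 0.40, camera adjusted p = 0.0263, adjusted p = 0.459 with an estimated correlation, and 0.0668 with the filter at a mean of 5 FPKM). Glial markers gave 8 higher and 0 lower in 12, with a median of 0.65 (camera adjusted p = 0.0142, adjusted p = 0.459 with an estimated correlation, and 0.229 with the filter at a mean of 5 FPKM). The dopamine list gave 4 higher and 0 lower in 16 (2 and 0 adjusted over the list alone, camera adjusted p = 0.341).

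Sperm, germ line, DNA replication and proteasome genes were lower in WLZ3 than in WLZ1. Major sperm protein genes fell in 20 of 27 cases with 0 rises (27 adjusted over the list alone). Log2 changes centred on -1.90 (camera adjusted p = 1.11e-09, and adjusted p = 0.418 with an estimated correlation). The WLZ3 libraries ranged from 7.29 to 53.3 FPKM for msp-57. In the other sperm genes 16 were lower and 4 higher of 56 (16 and 3 adjusted over the list alone), with a median of -0.80 (camera adjusted p = 3.23e-06, adjusted p = 0.459 with an estimated correlation, and 0.0668 with the filter at a mean of 5 FPKM). Oocyte and early embryo genes fell in 22 of 36 cases (24 adjusted over the list alone, median -0.20, camera adjusted p = 1.24e-10), germ line and P granule genes in 19 of 37 (median -0.17, camera adjusted p = 1.35e-08), DNA replication genes in 16 of 34 (median -0.14, camera adjusted p = 4.01e-09) and proteasome subunits in 22 of 34 (24 adjusted over the list alone, median -0.17, camera adjusted p = 4.56e-11), each with 0 rises and with adjusted p = 0.415 with an estimated correlation. mes-6 stood at 47.8 FPKM in WLZ1 and 38.1 in WLZ3, and the proteasome lid gene rpn-7 at 190 and 153 FPKM. Yolk protein genes fell in 2 of 6 cases with 0 rises, with a median of -0.24 (camera adjusted p = 0.00857, and adjusted p = 0.415 with an estimated correlation). Mitochondrial DNA genes were higher in WLZ3 in 8 of 12 cases and lower in 0 (10 and 0 adjusted over the list alone). Log2 changes had a median of 0.44 (camera adjusted p = 0.00846, and adjusted p = 0.418 with an estimated correlation). In this list ND5 went from 111 ± 6.82 to 165 ± 13.9 FPKM. Pathogen response genes gave 19 higher and 2 lower in 34, with a median of 0.41 (camera adjusted p = 0.00318, and adjusted p = 0.415 with an estimated correlation). The infection response gene irg-6 went from 7.87 ± 0.742 to 23.7 ± 3.77 FPKM. Lysozymes and antimicrobial peptides gave 52 higher and 10 lower in 86 (56 and 10 adjusted over the list alone, median 0.53, camera adjusted p = 0.00608, and adjusted p = 0.418 with an estimated correlation). C-type lectins gave 33 higher and 36 lower in 115 (37 and 37 adjusted over the list alone). The median was 0.11 and the mean -0.28, and camera called them downward (adjusted p = 0.0136, and adjusted p = 0.418 with an estimated correlation). This call was lost without WLZ1 replicate 1, 2 or 3, with medians of 0.22, 0.24 and 0.22 (adjusted p = 0.551, 0.12 and 0.737), with median-of-ratios scaling (adjusted p = 0.152) and with the filter at a mean of 5 FPKM, which left a median of 0.15 (adjusted p = 0.258). Without a WLZ1 library, lectins at 1 FPKM only in WLZ1 again left the test by the filter. Heat shock genes gave 5 higher and 8 lower in 32 (median -0.10, camera adjusted p = 0.0133). synMuv genes gave 1 and 8 in 22 (camera adjusted p = 0.000419). The abu and pqn genes gave 30 and 5 in 55 (31 and 7 adjusted over the list alone, camera adjusted p = 0.0142). Ribosomal protein genes gave 14 and 0 in 77 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0495). In that order, adjusted p was 0.415, 0.415, 0.459 and 0.757 with an estimated correlation. Camera called 20 lists in WLZ1 against N2 (8 up, 12 down), 27 in WLZ3 against N2 (10 up, 17 down) and 24 between the strains (14 up, 10 down), and 0 in each held with an estimated correlation.

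Most genes called in both strains moved the same way. Of 14862 genes, 4860 were called in the same direction against N2 in WLZ1 and WLZ3, 1610 higher and 3250 lower, where independent lists would share 1912, and 69 were called in opposite directions. The shared count was 2730 without N2 replicate 2 and 2898 without N2 replicate 3, and shared rises numbered 894 without WLZ3 replicate 1. The excess of shared falls depended on scaling, with 2723 rises and 2857 falls under median-of-ratios scaling and 2052 and 2022 under quantile normalization. Both contrasts used the same N2 libraries, and simulated strains with shared controls and no changed genes shared 0 calls, which is chance with no effect and does not measure the part due to shared controls. Across genes, which are not independent replicates, the changes in WLZ1 and WLZ3 had a Pearson r of 0.764 and a Spearman rho of 0.817, against 0.502 and 0.46 in the simulations. The covariance of the changes was 0.2791, against 0.0146 in the simulations, a difference of 0.265. The N2 libraries were not split between the contrasts, since one part would hold 1 library, so part of the excess may come from them. For 4372 of the shared genes (90%) the change was larger in WLZ1, with a median ratio of WLZ3 to WLZ1 of 0.58. Of the 4860, 2695 also differed between the strains, 2653 of them with the larger change in WLZ1, among these tnt-4, cut-2, cut-3 and nlp-39.

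**Figure D5:**
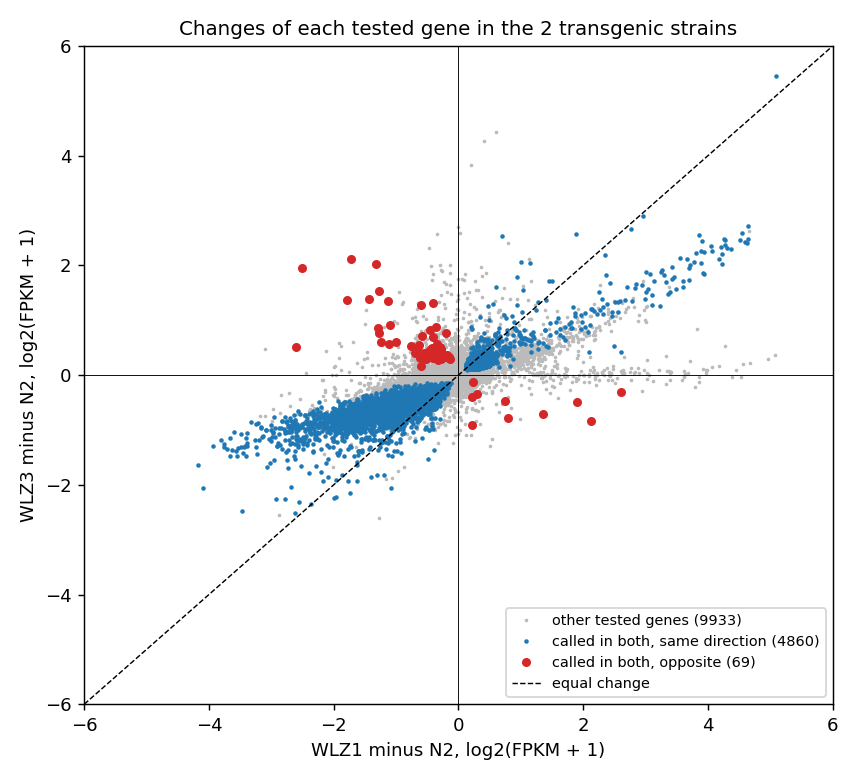
Log2 change in WLZ3 (y) against that in WLZ1 (x), each against N2, for every tested gene, with the line of equal change dashed. The 4860 genes called in the same direction lie mostly nearer the x axis than the line (median ratio 0.58), and 69 genes were called in opposite directions.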

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

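The contrast between the strains was planned, and the order of the genes, by the smaller of the 2 changes against N2, was chosen after the result was seen. In all, 69 genes were called in opposite directions against N2 in WLZ1 and WLZ3, and the direct test between the strains called all 69. That outcome follows from how they were picked and adds no separate support. Of these, 59 were lower in WLZ1 than in N2 and 10 were higher. Dixon's test for a single outlying library was not run on groups of 3.

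Of the 6 genes at the top of that order, M199.9 stood at 12.5 FPKM in N2, 1.45 in WLZ1 and 51.5 in WLZ3, a log2 difference between the strains of 4.467. clec-190, a C-type lectin gene that lies next to M199.9 on chromosome IV, stood at 15.1, 3.67 and 40.7 FPKM in the same order (3.156). Y49G5A.1 stood at 3.98, 0.54 and 21 FPKM (3.85) and F57G8.7 at 2.15, 0.259 and 12 FPKM (3.364). meic-1 stood at 4.9, 1.38 and 15.7 FPKM (2.81) and F59C6.18 at 2.69, 0.385 and 8.65 FPKM (2.813).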

How the results depend on the processing

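The limma-voom fit on recovered reads and the fit to protein-coding genes were chosen after the result was seen. Counts of calls and lists gave 127 values within 1.5 times the reported one and 10 outside it. Named genes gave 9357 values of the same direction and side of the threshold, 380 weaker, 1 stronger and 6 reversed, and lists 1147, 54 weaker and 6 reversed. The values for lists leave out the settings with an estimated correlation and with fry. With an estimated correlation camera called 0 lists in WLZ1 against N2, 0 in WLZ3 against N2 and 0 between the strains. fry, which asks whether a list moves on balance and not whether it differs from other genes, called 36 lists in WLZ1. The filter at a mean of 5 FPKM left 9524 genes and 6469 calls in WLZ1 against N2 and 3782 between the strains, because fewer genes were tested. For C-type lectins, the filter turned camera's direction in WLZ1 against N2 (median -0.14) and between the strains (median 0.146). Without 1 library, their median ranged from -0.152 to 0.093 and from 0.073 to 0.245. Camera's direction turned without WLZ1 replicate 2 against N2 (median -0.139), and between the strains without WLZ1 replicate 1, 2 or 3 (medians 0.218, 0.245 and 0.216). Quantile normalization reversed lrk-1 (0.177 in WLZ1, 0.11 in WLZ3, -0.067 between the strains), lonp-2 (0.122 in WLZ1) and pals-22 (0.101 in WLZ1), and median-of-ratios scaling reversed snb-1 (0.094 in WLZ1). Without a WLZ1 library, lectins at 1 FPKM only in WLZ1 failed the filter and left the test. For the other reversals the cause was not tested.

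Without 1 library, calls ranged from 8905 to 9913 in WLZ1 against N2, from 3013 to 5597 in WLZ3 against N2 and from 4369 to 6508 between the strains, and shared calls from 2730 to 5075. The lowest counts in WLZ3 and in the overlap came without N2 replicate 2 and, at 3204 and 2898, without N2 replicate 3. Of 9 same-number pairs of libraries, 2 correlated above 0.1 in their deviations from group means (range -0.145 to 0.244). With 3 libraries per group, this cannot show whether the replicate numbers mark batches. With a replicate block the counts were 9623, 4410 and 5429, with 4007 shared. On simulated data with 3 libraries per group, 40.8% of genes changed 1.5-fold were recovered.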

Other observations

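The tests of the X chromosome, scaling, all somatic tissue, neighbour pairs, males, T10H9.10 and the splits were chosen after the result was seen, as was the rule that picked the genes near 0 outside WLZ1. Genes on the X chromosome were lower in both strains. Among 1989 tested protein-coding genes on X, the median log2 change was -0.56 in WLZ1 and -0.25 in WLZ3, against -0.03 and 0.01 for 11747 autosomal genes (permutation p across genes 0.0001 in each, the smallest that 10000 permutations can give). The autosomes were not alike: chromosome V had medians of -0.304 and -0.088, and chromosomes I to IV lay between -0.045 and 0.084 in WLZ1 and between 0.01 and 0.052 in WLZ3. Within the neuronal, muscle and surface lists the medians of 109 X genes and 405 autosomal genes were -1.08 and -1.02 in WLZ1 (permutation p = 0.44) and -0.53 and -0.45 in WLZ3 (permutation p = 0.19). Genes are not independent replicates.

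Reads at T10H9.10 in both transgenic strains and none in N2 were set against the 3 genes around it. A duplication of the whole region needed pmp-5, snb-1 and syx-18 to rise, and their mean log2 change was -0.049 in WLZ1 and -0.095 in WLZ3. Reads from the construct counted at the worm locus needed the next gene upstream not to rise, and pmp-5 changed by -0.207 in WLZ1 and -0.146 in WLZ3. The reads may therefore come from the snb-1 promoter stretch of the construct, a hypothesis found and tested on the same data.

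Lower neuronal, muscle and cuticle lists with higher germ line lists in WLZ1 held under both other scalings, where the highest median among the muscle, collagen and synaptic vesicle lists was -0.924. Outside that test, the highest medians were -0.855 for moulting and -0.392 for neuropeptides (-0.795 as deposited). A lower share of all somatic tissue alike needed the intestine to fall with muscle, and the intestine median lay above that of muscle by 0.913 (95% bootstrap interval over genes 0.64 to 1.19). Fewer late embryos or larvae in the WLZ1 samples predicted lower mid-embryo transcription factors, a test written beforehand for a pattern seen in the same data. Their median was -0.617 (-0.75 to -0.47), with 2 higher and 26 lower of 34. Of the 34, 7 were also in the glia, epidermis, intestine, muscle or pharynx lists. An adult list whose members had been seen had a median of 0.183 (-0.03 to 0.74) over 7 measured genes. In WLZ3 the mid-embryo median was -0.2 (-0.27 to -0.14). Factors shared with tissue lists can fall with those tissues, so the test cannot tell a stage mix from lower expression in the tissues. The pattern may reflect the stage mix of the animals, and an effect of LRRK2 itself or of the strain, which the design names, stays open and untested.

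The 44 genes near 0 in N2 and WLZ3 and above 5 FPKM in all WLZ1 libraries lay closer together than random genes. They had 7 neighbour pairs within 50 kb, against 1.01 by chance (permutation p = 3e-05). The chance draws ignored families of adjacent related genes, such as clec-207 and clec-208, which can raise the count. Of the 44, 12 lay between 2689917 and 3640297 on chromosome II, bounds set by these genes. That stretch held 1.42% of protein-coding genes. A copy gain of that stretch needed the 144 other tested genes in it to rise, and their median was 0.069 (-0.03 to 0.16). Males among the WLZ1 animals needed male genes to rise, and their median ratio of reads was 0.6, below the bound of 1.5 set against males, yet of 11 members with at least 30 reads 4 were above 1.5 and 6 below 1, so the median decides nothing. Males could not be excluded by this list, and a strain difference stays open and untested.

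Splits of the 6 libraries of a contrast into 3 and 3 number 10, too few for a share under 0.05. For calls in WLZ1 against N2, 1 of the 10 splits gave as many as the real 10051, and the highest other gave 1. In WLZ3 against N2 it was 1 of 10 (real 5354, highest other 3), and between the strains 1 of 10 (real 6259, highest other 4). For lists, 8 of 10 splits gave as many as the real 20 in WLZ1 (highest other 25), 1 of 10 as many as 27 in WLZ3 (highest other 20) and 1 of 10 as many as 24 between the strains (highest other 23). For the overlap, 1 of 100 drawn splits of the 9 libraries gave as many as the real 4860, and that 1 was the real grouping. Most others mixed strains in the control group and shared 0 calls. With the 3 N2 libraries kept as controls and the strains mixed, drawn splits shared 1523, 1955 and 1383 calls. With the 3 WLZ3 libraries as controls, drawn splits shared 326 calls when N2 and WLZ1 stayed whole and 10 when they were mixed. The count thus depended on which libraries formed the control group, and the splits cannot exclude chance or the part due to shared controls. The highest other split gave 4436, with the WLZ1 libraries in the control role against mixed groups of N2 and WLZ3 libraries, which points to the structure of the samples.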
